A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

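RNA was sequenced from 24 libraries, 3 for each of 4 diploid yeast strains in each of 2 media, in synthetic complete medium with 2% raffinose at 30 °C and with 2% galactose or water for 2 h. Per the labels, poly(A) RNA was selected and libraries were made with a kit that does not keep the strand, and single reads of 50 nt were taken. Per the labels, the authors converted base calls with bcl2fastq and quantified reads with kallisto, whose version and target build were not given. The deposited estimated counts were made by kallisto, which splits reads shared between targets. The deposited TPM values were computed by the authors from those counts and the effective target lengths. The deposited lengths and effective lengths are other values, in bases per target, and were used only to describe the RPO21 targets and for the checks of the closing section. Library totals ran from 6443519 to 9383781 estimated counts, and TMM factors from 0.8979 to 1.091. Intervals and floors cover counting error only. The replicates are not stated to be separate cultures, so each p measures the spread between these samples, pooled over all groups. Chi-square per degree of freedom between libraries of a group without galactose was 85.6 to 272 in wild type, 13.4 to 35.3 in CTD10. The pooled spread may thus be too narrow, and p too small, in comparisons that use wild type without galactose. Each genotype is given as a single strain, and no spike-in was named, so levels are relative to all other transcripts.

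Estimated counts were tested in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3, by a quasi-likelihood fit to all 24 libraries with 1 mean per group, TMM factors, the low-count filter of edgeR and a prior count of 0.125. p values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Genes tested were 5848, of which 849 had reads split between targets, and those are uncertain. CPM are mean ± SD over 3 libraries, and log2 fold changes carry their SE. Groups with no counts were given a floor of 3 counts over the group, and those with few counts a ratio with its 95% counting interval. Fixed gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and members were also adjusted over the list alone. Of 630 list tests 233 passed with the preset correlation and 11 with the estimated correlation. Resemblance between libraries was measured as the correlation of residuals across genes, and same-numbered samples were taken as resembling each other in a comparison where every such correlation passed 0.1. Of 84 same-numbered pairs 71 did, with a mean of 0.27, against a mean of -0.13 for different-numbered pairs. The library numbers of the samples also run in order of replicate number over all groups. The labels do not say what the replicate number marks. The main test takes no account of it, and fits with it as a block are given as an alternative. The comparisons and the 30 gene lists were fixed before the data were examined, and so was the rule for naming genes. The list of unfolded protein response targets in the closing section is not one of the 30.

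Genes are named by that rule. RPO21, the GAL regulon and INO1 are always given. Called genes with a mean of at least 50 counts in a group and no overlap between groups follow, by size of change: up to 12 each way for galactose in wild type and for CTD10 against wild type without galactose, 10 each way for the other strains in that medium and 5 each way elsewhere. Up to 4 members of a list with the smallest p serve as its examples. Gene symbols came from the R64 annotation, by systematic identifier. No coordinates are given, because the build was not stated. The procedure was tested on simulated data with 5819 genes run. It recovered 37.3, 70.1 and 92.3% of genes changed 1.5-, 2- and 4-fold between 2 groups with 6 false calls, and 5.97, 46.3 and 87.7% in an interaction with 5 false calls. A comparison with no change gave 0 false calls. A planted list of 20 genes passed with an adjusted p of 6.6e-65, and 0 of 29 random lists passed. The simulation drew genes independently of each other and gave each gene 1 spread in all groups. It therefore does not test camera where genes vary together, nor false calls where 1 group varies more than others.

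The alternatives tried were the Wald test of DESeq2 1.42.0, RLE factors, no low-count filter, limma on log2 TPM with a pseudocount of 1, the replicate number as a block, a fit to the compared libraries alone, a minimum change of log2 1 and each library left out in turn. A fit without the 4 libraries without galactose whose ADH2 exceeded 5000 CPM was added after the data were seen. Each comparison of 3 against 3 libraries was also run on the 10 ways to split the 6 libraries, and each interaction on 100 splits drawn with a fixed seed. Splits that part all pairs were compared where same-numbered samples resembled each other. Nothing deposited was left out.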

Results

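Messenger RNA was sequenced from 4 diploid strains of the budding yeast Saccharomyces cerevisiae in the BY4743 background, each grown in synthetic complete medium with 2% raffinose at 30 °C. Cultures received either 2% galactose for 2 h or water, and 3 libraries were made per strain and medium, giving 24 libraries in 8 groups. The strains differed in RPO21 (YDL140C), which encodes the largest subunit of RNA polymerase II. Its C-terminal domain (CTD), a tail of repeated heptads, was intact in wild type and shortened to 10 repeats in CTD10. In CTD10_FUS and CTD10_TAF15 the low complexity domain of FUS or of TAF15, both RNA-binding proteins of human cells, was joined to the shortened tail. All strains carried 14 PP7 repeats at the start of GAL10. Library totals were 6443519 to 9383781 estimated counts, lowest in CTD10_TAF15 with galactose replicate 3 and highest in CTD10_TAF15 with galactose replicate 2, and 5848 genes were tested. The authors used a target for RPO21 that follows the strain label. Its length was 5202 bases in the wild-type libraries and 384 bases shorter in the CTD10 libraries. It was 639 bases longer than in CTD10 in the CTD10_FUS libraries and 621 bases longer in the CTD10_TAF15 libraries. The counts of GAL1, GAL10, GAL7 and GAL2 made up 1.87 to 5.83% of each library with galactose and 0.00226 to 0.00617% of each library without it.

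RPO21 messenger RNA was present in every strain. Without galactose it averaged 658 ± 46.1 CPM (normalised read count; mean ± SD, n = 3 libraries per group throughout) in wild type, 777 ± 64.7 in CTD10, 904 ± 69.8 in CTD10_FUS and 841 ± 86.3 in CTD10_TAF15. It was higher than in wild type in CTD10_FUS (log2 fold change 0.46 ± 0.10, SE throughout) and in CTD10_TAF15 (log2 0.35 ± 0.10), and the value for CTD10 did not pass the test (log2 0.24 ± 0.10, adjusted p = 0.071). With galactose the 3 mutant values, log2 0.06 ± 0.10, 0.27 ± 0.10 and 0.29 ± 0.10 in CTD10, CTD10_FUS and CTD10_TAF15, did not pass either. With the replicate number as a block RPO21 passed in CTD10 without galactose (adjusted p = 0.042) and in CTD10_FUS and CTD10_TAF15 with galactose (adjusted p = 0.0407 and 0.0295). The target was shorter or longer than the wild-type one in each mutant, which alone can move its count. The CTD10_TAF15 call ended in 4 of the 6 fits that left out 1 library, with adjusted p = 0.106 without CTD10_TAF15 without galactose replicate 1 (log2 0.28).

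The first comparison was the response of wild type to galactose. GAL7 (YBR018C), which encodes galactose-1-phosphate uridylyltransferase, rose from 0.983 ± 0.184 to 7986 ± 1400 CPM, a log2 fold change of 12.97 ± 0.37. The galactokinase gene GAL1 (YBR020W) rose from 17.2 ± 4.11 to 23810 ± 4140 CPM (log2 10.44 ± 0.30), and GAL10 (YBR019C), the epimerase gene that carries the PP7 repeats, from 17.5 ± 8.98 to 10670 ± 2870 CPM (log2 9.26 ± 0.54). The permease gene GAL2 (YLR081W) rose by 10.31 ± 0.50 on the log2 scale, the sensor gene GAL3 (YDR009W) by 3.89 ± 0.19 and GAL80 (YML051W), which encodes the repressor of the activator Gal4, by 3.05 ± 0.14. Of the 11 tested genes of the GAL regulon 9 rose and 0 fell, and adjusted over the list alone 9 rose and 1 fell. The remaining calls were GCY1 (YOR120W) at 3.62 ± 0.43, the uracil permease gene FUR4 (YBR021W), a neighbour of GAL1, at 3.06 ± 0.37, and MTH1 (YDR277C), a regulator of hexose transporter genes, at 1.37 ± 0.18. The phosphoglucomutase gene PGM2 stood at -1.54 ± 0.58 (adjusted p = 0.0707) and PCL10 at 0.15 ± 0.42, and PGM2 at -0.21 without wild type without galactose replicate 3. The list as a whole was shifted upward against all other genes (camera adjusted p = 1.1e-87, and adjusted p = 1.89e-09 with an estimated correlation). Further high calls, YDR010C at 4.14 ± 0.46 and YOR121C at 3.30 ± 0.40, are open reading frames next to or overlapping GAL3 and GCY1, and the library kit did not keep the strand.

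Genes for the use of other carbon sources were lower with galactose in wild type. ACS1 (YAL054C), the acetyl-CoA synthetase gene, fell from 3002 ± 2380 to 4.77 ± 3.29 CPM (log2 -9.32 ± 1.54), ADH2 (YMR303C), the glucose-repressed alcohol dehydrogenase gene, which shares a few reads with other targets, from 13630 ± 10400 to 65.2 ± 25.6 CPM (log2 -7.71 ± 1.13), and the aldehyde dehydrogenase gene ALD4 by -5.47 ± 0.73 as a log2 change. The peroxisomal fatty acid oxidation genes FOX2 and POX1 changed by -7.29 ± 1.20 and -6.93 ± 1.03, and the acetate transporter gene ADY2 by -9.20 ± 1.91. Of 16 glucose-repressed genes of carbon use 10 fell, 13 when adjusted over the list alone (median log2 -3.21, camera adjusted p = 6.91e-08, and adjusted p = 0.219 with an estimated correlation). Of 24 general stress genes 16 fell and 1 rose, 20 and 1 when adjusted over the list alone. They included the small heat shock protein gene HSP12 at -4.51 ± 0.90, the glycogen phosphorylase gene GPH1 at -3.92 ± 0.80 and, upward, DDR48 at 1.33 ± 0.27, which shares reads and is uncertain. The list median was -2.16 (camera adjusted p = 1.15e-05, and adjusted p = 0.649 with an estimated correlation). Of 8 hexose transporter genes 4 fell and 6 did so when adjusted over the list alone (camera adjusted p = 9.98e-06, and adjusted p = 0.103 with an estimated correlation). Among them HXT7, which shares reads with HXT6 and is uncertain, was at -2.23 ± 0.22. These groups differed between the wild-type libraries without galactose. There the mean log2 CPM of the glucose-repressed list was 7.54, 9.34 and 8.71, and ADH2 stood at 2140, 16300 and 22500 CPM, in replicates 1, 2 and 3.

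Other groups moved by less in wild type. Of 10 histone genes 7 fell, 7 also when adjusted over the list alone, including the linker histone gene HHO1 (YPL127C) at -1.23 ± 0.13, HTA1, which shares reads and is uncertain, at -1.02 ± 0.18 and HTB1 at -0.80 ± 0.14 (camera adjusted p = 1e-06, and adjusted p = 0.29 with an estimated correlation). Of 20 heat shock chaperone genes 6 rose, 6 also when adjusted over the list alone, with the Hsp70 gene SSA2 at 1.58 ± 0.21 and the Hsp90 gene HSC82 at 0.90 ± 0.14, both of which share reads with close copies and are uncertain. That list had a camera adjusted p = 9.43e-04, and adjusted p = 0.428 with an estimated correlation. Of 119 genes of cytosolic ribosomal proteins 20 rose, 67 when adjusted over the list alone, at a median log2 of 0.50 (camera adjusted p = 4.75e-16, and adjusted p = 0.649 with an estimated correlation). Many of these share reads with their paralogs. In all, 436 genes rose and 685 fell, 1121 together, of which 948 had no overlap between the groups. No overlap was seen in 26.4% of all tested genes, against 10% by chance. The spread shared by all groups may be too narrow for wild type without galactose, so the count of calls can be too high. Leaving out 1 library gave between 379 genes (without wild type without galactose replicate 3) and 2388 genes (without wild type without galactose replicate 1, 1226 higher and 1162 lower). In 5 of the 6 fits the count was over 1.5 times from the full count. The count was 27 (15 higher and 12 lower) when only these 6 libraries were fitted and 84 without the libraries of high ADH2, an alternative chosen after the data were seen.

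**Figure D1:**
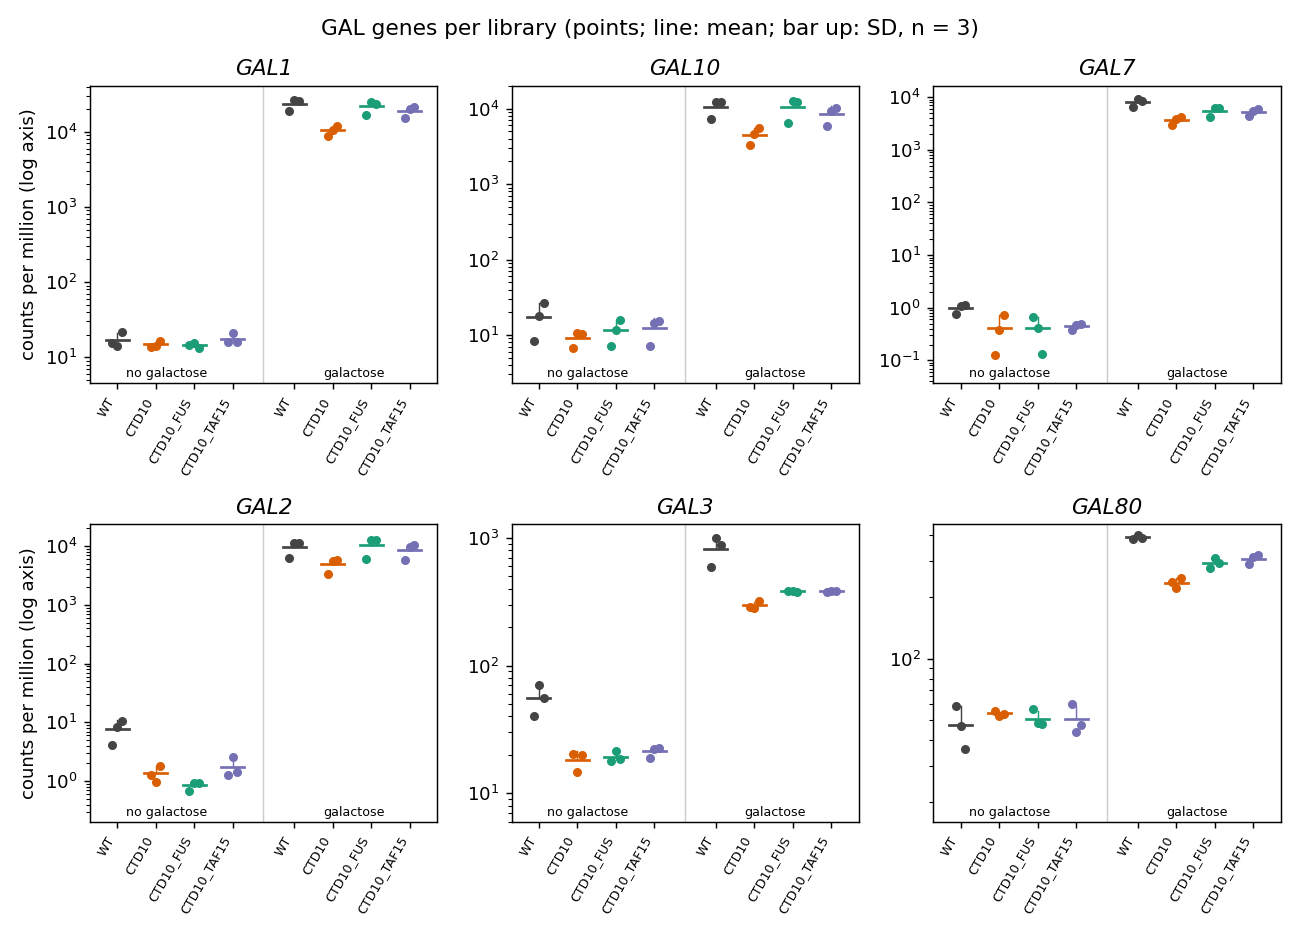
Normalised read counts (CPM) of GAL1, GAL10, GAL7, GAL2, GAL3 and GAL80 on log axes, by strain and medium, with points for single libraries, horizontal lines for group means and bars of 1 SD upward (n = 3). All libraries with galactose lie above all libraries without it, and with galactose the CTD10 points lie below the wild-type points for GAL1.

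The GAL genes responded in each mutant as well. In CTD10, GAL7 rose by 13.06 ± 0.39 on the log2 scale, GAL2 by 11.80 ± 0.55, GAL1 by 9.47 ± 0.29, from 14.8 ± 1.62 to 10500 ± 1640 CPM, and GAL10 by 8.94 ± 0.54. GAL3 rose by 4.01 ± 0.20, GAL80 by 2.12 ± 0.14 and GCY1 by 3.21 ± 0.43. Of the 11 GAL regulon genes 8 rose and 9 did so when adjusted over the list alone (adjusted p = 2.36e-14 with an estimated correlation). Only 14 genes were called in CTD10, all of them upward. An unadjusted p under 0.05 was found for 177, less than a share of 0.05 of the 5848 tested genes. A fit to these 6 libraries called 17, with 354 at an unadjusted p under 0.05. The spread shared by all groups may be too wide for CTD10, so the count does not show a lack of response. All 14 had no overlap between the groups, which 12.2% of all tested genes also showed, against 10% by chance. The counts without 1 library were 13 to 14. The GAL regulon gene MTH1, called here at 0.95 ± 0.18, lost its call in 5 of those 6 fits, with adjusted p = 0.234 without CTD10 without galactose replicate 2 (log2 0.88). Samples of the same replicate number resembled each other across both media in CTD10, and a fit with the replicate number as a block called 23 genes.

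In CTD10_FUS, GAL7 rose by 13.69 ± 0.40, GAL2 by 13.56 ± 0.59, GAL1 by 10.56 ± 0.30, from 14.4 ± 1.21 to 21800 ± 4390 CPM, and GAL10 by 9.81 ± 0.55 on the log2 scale. GAL3 rose by 4.30 ± 0.20, GAL80 by 2.53 ± 0.14 and MTH1 by 1.26 ± 0.18, and 9 of the 11 GAL regulon genes rose, 9 also when adjusted over the list alone (camera adjusted p = 7.63e-162, and adjusted p = 2.32e-11 with an estimated correlation). HXT7, a high-affinity hexose transporter gene that shares reads with HXT6, fell (log2 -1.77 ± 0.22). The largest falls were those of PDH1, of propionate use, at -2.88 ± 0.63 and the transporter gene FAT3 at -2.53 ± 0.53, and both calls ended in 4 of 6 fits without 1 library. The highest adjusted p was 0.304 for PDH1, without CTD10_FUS without galactose replicate 2 (log2 -1.67), and 0.176 for FAT3, without CTD10_FUS with galactose replicate 2 (log2 -2.18). Of 25 genes of amino acid synthesis 1 rose, 9 when adjusted over the list alone (camera adjusted p = 2.58e-09, and adjusted p = 0.309 with an estimated correlation). In all, 30 genes rose and 19 fell, 49 together, 49 of which had no overlap between the groups, against 27.3% of all tested genes and 10% by chance. The count ran from 15 (without CTD10_FUS without galactose replicate 2) to 40 (without CTD10_FUS with galactose replicate 1) when 1 library was left out. In 5 of the 6 fits the count was over 1.5 times from the full count. The balance of directions depended on the tool and the scaling. DESeq2 called 232 genes (113 higher and 119 lower), limma on TPM 277 (30 higher and 247 lower) and a fit with the replicate number as a block 239 (130 higher and 109 lower). A fit to these 6 libraries called 24 and a fit without the libraries of high ADH2 154 (64 higher and 90 lower).

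In CTD10_TAF15, GAL7 rose by 13.49 ± 0.39, GAL2 by 12.24 ± 0.55, GAL1 by 10.07 ± 0.30, from 17.6 ± 2.72 to 18950 ± 3160 CPM, and GAL10 by 9.42 ± 0.55 on the log2 scale. GAL3 rose by 4.16 ± 0.20, GAL80 by 2.61 ± 0.14 and MTH1 by 1.00 ± 0.18. Of the 11 GAL regulon genes 9 rose, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 6.18e-109, and adjusted p = 3.42e-10 with an estimated correlation). HXT7 fell (log2 -1.39 ± 0.22). Ribosomal protein genes stood higher, with 10 of 119 called and 108 when adjusted over the list alone (median 0.55, camera adjusted p = 1.41e-28, and adjusted p = 0.404 with an estimated correlation). Of 24 general stress genes 8 fell, and 21 fell and 1 rose when adjusted over the list alone (camera adjusted p = 8.4e-08, and adjusted p = 0.439 with an estimated correlation). Of 16 glucose-repressed genes of carbon use 3 fell, 7 when adjusted over the list alone (median -1.43, camera adjusted p = 4.43e-04, and adjusted p = 0.404 with an estimated correlation). Among named genes the largest falls were of ADY2 by -6.30 ± 1.61, ACS1 by -4.70 ± 1.22, FOX2 by -3.93 ± 1.01, POX1 by -3.52 ± 0.86 and the catalase gene CTA1 by -3.17 ± 0.86 on the log2 scale. These calls ended in 4, 5, 4, 3 and 5 of the 6 fits without 1 library. The highest adjusted p, 0.258, 0.226, 0.275, 0.226 and 0.358, were all found without CTD10_TAF15 without galactose replicate 2 (log2 -3.39, -3.05, -2.16, -2.14 and -1.59). The libraries without galactose differed in such genes, with ADH2 at 510, 11300 and 4140 CPM in replicates 1, 2 and 3. In all, 191 genes rose and 220 fell, 411 together, of which 400 had no overlap between the groups, against 28.7% of all tested genes and 10% by chance. Leaving out 1 library gave 19 genes (without CTD10_TAF15 with galactose replicate 2) to 1192 genes (without CTD10_TAF15 without galactose replicate 1). In 5 of the 6 fits the count was over 1.5 times from the full count. Same-numbered samples resembled each other here, and a fit with the replicate number as a block called 1397 genes (801 higher and 596 lower), against 11 from these 6 libraries alone, all higher. The balance of directions depended on the tool and the scaling, with 452 higher and 440 lower by DESeq2 and 88 higher and 872 lower by limma on TPM.

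Whether the response to galactose differed between strains was tested as an interaction. Between CTD10 and wild type, GAL80 rose less in CTD10 (interaction -0.93 ± 0.18, adjusted p = 0.0192), as did FUR4 (-2.14 ± 0.50, adjusted p = 0.0453). Some carbon use genes, lower with galactose in wild type, differed the other way, with ACS1 at 9.27 ± 1.78, ADH2 at 8.21 ± 1.36 and FOX2 at 7.39 ± 1.45. Of 30 gene lists tested for this interaction, 10 passed with the preset correlation and 0 with an estimated correlation. In all, 60 genes responded more positively in CTD10 and 28 less, 88 together. For CTD10_FUS 3 genes differed from wild type: KAR2 (YJL034W), the chaperone of the endoplasmic reticulum (-1.42 ± 0.25), its partner JEM1 (YJL073W) (-0.93 ± 0.13) and MCD4 (YKL165C), an enzyme of membrane anchor synthesis (-1.41 ± 0.22). For CTD10_TAF15 they were KAR2 (-1.45 ± 0.25) and JEM1 (-0.90 ± 0.13). KAR2 had risen with galactose in wild type from 525 ± 33.4 to 1470 ± 477 CPM and stood at 521 ± 32.3 and 545 ± 76.5 CPM in CTD10_FUS. Between the fused strains and CTD10 the edgeR test called 0 genes, with 161 (CTD10_FUS) and 496 (CTD10_TAF15) genes at an unadjusted p under 0.05, and DESeq2 called 0 and 0. Over the GAL regulon the lowest adjusted p was 0.0192 for CTD10 against wild type, 0.0601 for CTD10_FUS, 0.312 for CTD10_TAF15, and 0.934 and 0.526 for CTD10_FUS and CTD10_TAF15 against CTD10. The CTD10 count ran from 4 (without wild type with galactose replicate 2) to 1037 (without wild type without galactose replicate 1), over 1.5 times from the full count in 11 of 12 fits, with 28 more positive and 46 less so without wild type with galactose replicate 3, and of the genes named only JEM1 in CTD10_FUS kept its call in all 12. The call of GAL80 ended in 8 of the 12 fits (highest adjusted p = 0.0738, log2 -0.92, without wild type with galactose replicate 2) and that of FUR4 in 10 (adjusted p = 0.137, log2 -1.97, without wild type without galactose replicate 3). Those of KAR2 ended in 9 fits in each fused strain (adjusted p = 0.134, log2 -1.41, without CTD10_FUS with galactose replicate 2, and adjusted p = 0.174, log2 -1.35, without wild type with galactose replicate 2). The counts ran from 1 (without wild type with galactose replicate 2) to 22 (without wild type without galactose replicate 1) for CTD10_FUS. For CTD10_TAF15 they ran from 0 (without CTD10_TAF15 without galactose replicate 3) to 15 (without wild type without galactose replicate 1). The counts for CTD10, CTD10_FUS and CTD10_TAF15 were 0, 0 and 0 without the libraries of high ADH2 and 31, 0 and 0 from the compared libraries alone.

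The strains were then compared without galactose, in raffinose alone, where each mutant differs from wild type in its CTD and also in its marker label and isolate. In CTD10, genes of amino acid synthesis stood higher than in wild type: HIS4 (YCL030C), of histidine synthesis, at 339 ± 154 against 95.8 ± 6.14 CPM (log2 1.82 ± 0.33), CPA2, a carbamoyl phosphate synthase gene, at log2 1.73 ± 0.34, and TRP5, of tryptophan synthesis, at 0.91 ± 0.13. Of the 25 Gcn4 targets tested 18 were higher and 0 lower, 22 and 0 when adjusted over the list alone (median 0.91, camera adjusted p = 5.33e-10, and adjusted p = 0.363 with an estimated correlation). DUR12 (YBR208C), the urea amidolyase gene, rose from 82.8 ± 6.06 to 233 ± 9.61 CPM (log2 1.49 ± 0.10), and the largest increase was that of YDR042C, a gene of unknown function, from 1.03 ± 0.672 to 26.8 ± 1.33 CPM (log2 4.69 ± 0.44). Of 32 proteasome genes 22 were higher and 28 when adjusted over the list alone, by small amounts such as 0.52 ± 0.10 for PUP3 and 0.40 ± 0.08 for PRE7 (median 0.30, camera adjusted p = 4.16e-08, and adjusted p = 0.385 with an estimated correlation). Genes of RNA polymerase II subunits were also higher, 5 of the 10 tested, which include RPO21 (not called), and 6 when adjusted over the list alone, with RPB4 at 0.40 ± 0.09 (camera adjusted p = 0.0037, and adjusted p = 0.385 with an estimated correlation).

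Genes lower in CTD10 than in wild type without galactose included many with few transcripts. ADH7 (YCR105W), an alcohol dehydrogenase gene, had 0 counts over the CTD10 group against 275 in wild type and was at least 94.1-fold lower (floor of 3 counts over the group). COS10 (YNR075W) fell from 11.3 ± 3.40 to 0.252 ± 0.132 CPM (log2 -5.41 ± 0.59), YDR541C (YDR541C) by a log2 change of -5.46 ± 0.42 and GPM2 by one of -6.14 ± 1.09. Haploid-specific genes, which diploid cells repress, were lower too: of 10 tested 7 fell, 7 also when adjusted over the list alone (median -1.22, camera adjusted p = 2.26e-06, and adjusted p = 0.0237 with an estimated correlation). They included GPA1 (YHR005C) and STE4, subunits of the pheromone G protein, at -2.50 ± 0.37 and -1.52 ± 0.25, and RME1, a repressor of meiosis, at -1.53 ± 0.21. STE3 (YKL178C), the receptor gene of alpha cells, was at -3.58 ± 0.33. Of 14 early meiosis genes 7 fell and 2 rose, 8 and 2 when adjusted over the list alone. These included the recombinase gene DMC1 at -3.56 ± 0.47, MEI4 at -3.22 ± 0.51 and, upward, REC104 at 1.93 ± 0.39 (camera adjusted p = 0.0135, and adjusted p = 0.363 with an estimated correlation). GAL2 and GAL3 were lower in this medium, at -2.46 ± 0.48 and -1.60 ± 0.19. They were 2 of the 11 GAL regulon genes (0 higher and 2 lower when adjusted over the list alone). The share of counts in GAL1, GAL10, GAL7 and GAL2 differed between the wild-type libraries, at 0.00288, 0.00433 and 0.00617% in replicates 1, 2 and 3. In CTD10 it was 0.00226, 0.00265 and 0.00311%.

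The same comparison held the carbon use and stress genes that differed between wild-type libraries. Of 16 glucose-repressed genes 10 were lower in CTD10 and 14 when adjusted over the list alone, with ADH2 at -5.40 ± 1.02 and ACS1 at -5.50 ± 1.26 (camera adjusted p = 1.25e-04, and adjusted p = 0.363 with an estimated correlation). Of 24 general stress genes 13 were lower, 17 when adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.632 with an estimated correlation). The glycolytic enolase gene ENO1, which shares reads with ENO2, stood at -2.89 ± 0.37, and 5 of 16 glycolytic genes were lower, 5 also when adjusted over the list alone (camera adjusted p = 0.06). INO1, of inositol synthesis, ranged widely in wild type (99.4 ± 135 CPM). It did not pass in any mutant, at -1.73 ± 0.98 in CTD10, -2.32 ± 1.01 in CTD10_FUS and -1.91 ± 0.99 in CTD10_TAF15, and had values of 0.50 in CTD10, -0.09 in CTD10_FUS and 0.32 in CTD10_TAF15 without wild type without galactose replicate 1. In all, 590 genes were higher and 940 lower in CTD10, 1530 together, and among changes of at least 2-fold 39 were higher and 507 lower. Of the 1530, 1344 had no overlap between the groups, against 32% of all tested genes and 10% by chance. Here too the shared spread may be too narrow for wild type without galactose. Leaving out 1 library gave 858 genes (without wild type without galactose replicate 3) to 2526 (without wild type without galactose replicate 1), with 3 of 6 counts over 1.5 times from the full count. Same-numbered samples resembled each other, and the count was 2369 with the replicate number as a block, 354 from these 6 libraries alone and 549 without the libraries of high ADH2.

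CTD10_FUS cells without galactose differed from wild type in many of the same groups. CAR1 (YPL111W), the arginase gene, was higher at 264 ± 31.3 against 68.4 ± 8.13 CPM (log2 1.95 ± 0.27), as were HIS4 (1.79 ± 0.33), CPA2 (1.74 ± 0.34), the lysine synthesis gene LYS1 (1.55 ± 0.32) and DUR12 (1.45 ± 0.10). Of the 25 Gcn4 targets 11 were higher, 13 when adjusted over the list alone (median 0.74, camera adjusted p = 2.72e-10, and adjusted p = 0.393 with an estimated correlation). ADH7 had 2 counts against 275, a ratio of 132 (95% counting interval 36.1 to 1090), COS10 was at -5.32 ± 0.59, YDR541C at -4.65 ± 0.40 and STE3 at -4.29 ± 0.35. Of 10 haploid-specific genes 6 fell, 6 also when adjusted over the list alone, with GPA1 at -2.15 ± 0.36 and AXL1, needed for the axial budding of haploid cells, at -0.92 ± 0.16 (camera adjusted p = 1.06e-06, and adjusted p = 0.0187 with an estimated correlation). Of 14 early meiosis genes 7 fell and 1 rose, 7 and 1 when adjusted over the list alone, with DMC1 at -3.79 ± 0.48 and MEI4 at -3.58 ± 0.54 (camera adjusted p = 5.49e-04, and adjusted p = 0.247 with an estimated correlation). GAL2 and GAL3 were lower at -3.15 ± 0.52 and -1.52 ± 0.19. In all, 212 genes were higher and 499 lower, 711 together, of which 638 had no overlap between the groups, against 20.7% of all tested genes and 10% by chance. Without 1 library the count was 406 (CTD10_FUS without galactose replicate 3) to 1474 (wild type without galactose replicate 1), over 1.5 times from the full count in 3 of 6 fits, and it was 106 from these 6 libraries alone and 205 without the libraries of high ADH2.

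In CTD10_TAF15 without galactose, CAR1 stood at 296 ± 98.0 CPM (log2 2.12 ± 0.27 against wild type), HIS4 at 1.59 ± 0.33, DUR12 at 1.44 ± 0.10 and the transporter gene MCH4 at 1.39 ± 0.22. Of the 25 Gcn4 targets 8 were higher, 8 also when adjusted over the list alone (median 0.50, camera adjusted p = 3.85e-06, and adjusted p = 0.541 with an estimated correlation). RDS1 (YCR106W), a zinc cluster transcription factor gene, fell from 36.5 ± 7.64 to 0.404 ± 0.0557 CPM (log2 -6.44 ± 0.76). ADH7 was at least 96.6-fold lower, COS10 at -5.70 ± 0.60, STE3 at -4.58 ± 0.36 and the permease gene UGA4 at -4.19 ± 0.70. Of 10 haploid-specific genes 6 fell, 6 also when adjusted over the list alone, with GPA1 at -2.11 ± 0.36 and STE4 at -1.57 ± 0.25 (camera adjusted p = 2.72e-06, and adjusted p = 0.0206 with an estimated correlation). Of 14 early meiosis genes 5 fell and 1 rose, 6 and 1 when adjusted over the list alone, with DMC1 at -3.69 ± 0.47 (camera adjusted p = 0.00146, and adjusted p = 0.297 with an estimated correlation). GAL2 and GAL3 were lower at -2.10 ± 0.46 and -1.38 ± 0.18. In all, 198 genes were higher and 393 lower, 591 together, of which 523 had no overlap between the groups, against 17.4% of all tested genes and 10% by chance. The count was 370 without CTD10_TAF15 without galactose replicate 3 and 926 without wild type without galactose replicate 1, the lowest and highest of 6, and 2 of them were over 1.5 times from the full count. A fit to these 6 libraries alone called 46 genes, the blocked fit 1050 and the fit without the libraries of high ADH2 248.

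**Figure D2:**
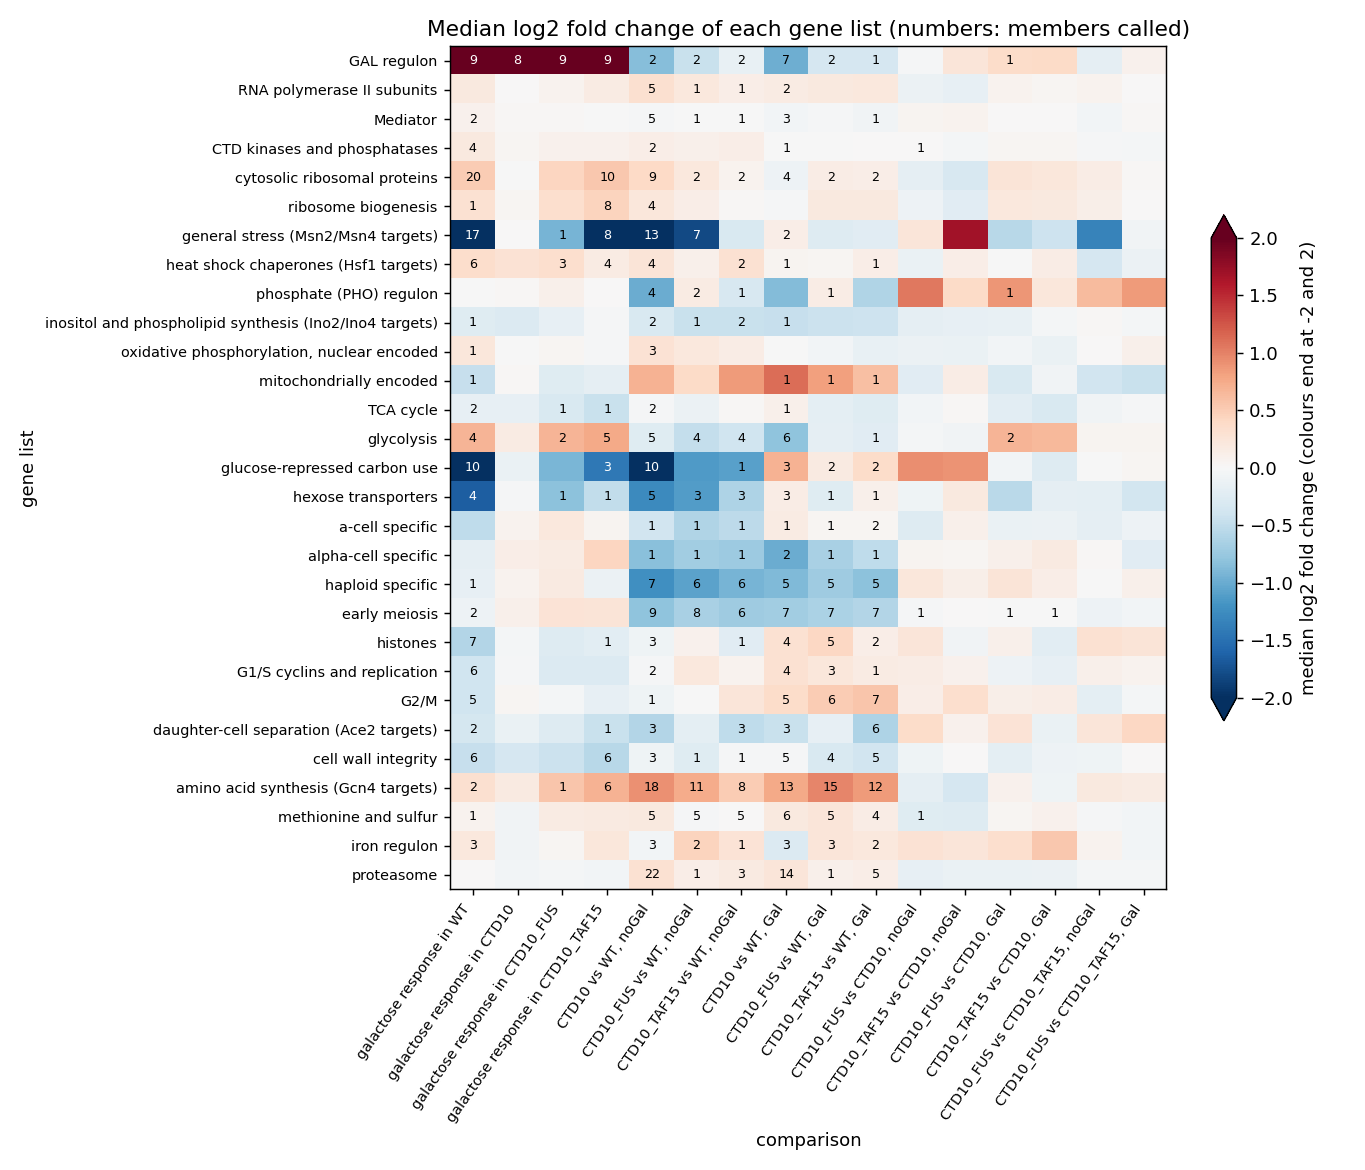
Median log2 fold change of 29 gene lists (rows) in 16 comparisons (columns), with the number of members past an adjusted p of 0.05 printed in each cell and colours ending at log2 -2 and 2. The haploid-specific list is below 0 in all 6 comparisons of a mutant with wild type and the amino acid synthesis list is above 0 in the same 6.

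With galactose, CTD10 had lower levels of the induced GAL genes than wild type. GAL1 stood at 10500 ± 1640 against 23810 ± 4140 CPM (log2 -1.18 ± 0.20, adjusted p = 0.000557), GAL7 at -1.11 ± 0.22, GAL3 at -1.48 ± 0.18, GAL80 at -0.74 ± 0.13 and FUR4 at -1.51 ± 0.35. GAL10 was at -1.24 ± 0.38 (adjusted p = 0.0304), a call that ended in 4 of the 6 fits without 1 library. The highest adjusted p was 0.113, without CTD10 with galactose replicate 1 (log2 -1.07). GAL2 did not pass at -0.98 ± 0.34 (adjusted p = 0.0531), and passed with the replicate number as a block (-0.97, adjusted p = 2.37e-04). Of the 11 GAL regulon genes 7 were lower, 8 when adjusted over the list alone (median -0.98, camera adjusted p = 1.29e-06, and adjusted p = 0.044 with an estimated correlation). Glycolytic genes were lower, 6 of 16 and 11 when adjusted over the list alone, including FBA1, the aldolase gene, at -0.72 ± 0.14 and TPI1 at -1.05 ± 0.27 (camera adjusted p = 1.23e-06, and adjusted p = 0.289 with an estimated correlation). Gcn4 targets were higher, 13 of 25 and 15 when adjusted over the list alone, with HIS4 at 1.97 ± 0.33 and CPA1 at 1.39 ± 0.19 (camera adjusted p = 4.46e-10, and adjusted p = 0.289 with an estimated correlation). Proteasome genes were higher in 14 of 32 cases, 17 when adjusted over the list alone (PUP3 0.59 ± 0.10, camera adjusted p = 1.23e-06, and adjusted p = 0.443 with an estimated correlation). Of 10 haploid-specific genes 5 were lower, 5 also when adjusted over the list alone, STE4 by a log2 change of -1.59 ± 0.25 (camera adjusted p = 2.09e-04, and adjusted p = 0.0655 with an estimated correlation).

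Among other genes, YDR042C was higher again, at 4.87 ± 0.44. Genes lower than in wild type included ADH7, with 2 counts against 205 (ratio 110, 95% counting interval 30.1 to 915), YDR541C at -5.08 ± 0.41 and COS10 at -4.65 ± 0.54. INO1 was at -1.31 ± 0.99 in CTD10, -2.07 ± 1.03 in CTD10_FUS and -1.66 ± 1.01 in CTD10_TAF15, none of which passed. It was at 0.58 in CTD10, -0.18 in CTD10_FUS and 0.23 in CTD10_TAF15 without wild type with galactose replicate 1. In all, 439 genes were higher and 534 lower in CTD10, 973 together, of which 960 had no overlap between the groups, against 39.7% of all tested genes and 10% by chance. The count was 578 without CTD10 with galactose replicate 2 and 785 without CTD10 with galactose replicate 1, the lowest and highest, with 2 of 6 over 1.5 times from the full count. Same-numbered samples resembled each other, and the blocked fit called 1539 genes.

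In CTD10_FUS with galactose, the structural GAL genes did not pass the test against wild type, with GAL1 at 21800 ± 4390 CPM and a log2 change of -0.13 ± 0.20 (adjusted p = 0.752), GAL10 at -0.04 ± 0.38, GAL2 at 0.10 ± 0.33 and GAL7 at -0.54 ± 0.22 (adjusted p = 0.121). Of these GAL7 passed with the replicate number as a block (-0.54, adjusted p = 0.0172). GAL3 was lower at -1.11 ± 0.17, from 826 ± 211 in wild type to 382 ± 4.38 CPM, and GAL80 at -0.42 ± 0.13. The GAL80 call ended in each of the 6 fits without 1 library (highest adjusted p = 0.124, log2 -0.38, without CTD10_FUS with galactose replicate 1). Of the 11 GAL regulon genes 2 were lower, and the list did not pass (camera adjusted p = 0.0565). Of 25 Gcn4 targets 15 were higher, 19 when adjusted over the list alone, with HIS4 at 2.27 ± 0.34 and LYS9 at 1.99 ± 0.30 (median 0.97, camera adjusted p = 7.98e-18, and adjusted p = 0.267 with an estimated correlation). Of 10 histone genes 5 were higher, 7 when adjusted over the list alone, with HHO1 at 0.70 ± 0.13 (camera adjusted p = 7.97e-05, and adjusted p = 0.346 with an estimated correlation). Genes expressed at G2/M were higher in 6 of 10 cases, 7 when adjusted over the list alone, with the polo kinase gene CDC5 at 0.50 ± 0.11 (camera adjusted p = 2.56e-04, and adjusted p = 0.287 with an estimated correlation). ADH7 had 2 counts against 205 (ratio 101, 95% counting interval 27.6 to 840), COS10 was at -4.97 ± 0.57 and ALD4, low in wild type with galactose, at 2.65 ± 0.64. In all, 276 genes were higher and 471 lower, 747 together, of which 737 had no overlap, against 35% of all tested genes and 10% by chance. Without 1 library the count was 479 (wild type with galactose replicate 2) to 611 (wild type with galactose replicate 3), with 2 of 6 over 1.5 times from the full count. Same-numbered samples resembled each other, and the blocked fit called 1299 (578 higher and 721 lower). The balance of directions was 408 higher and 497 lower by DESeq2 and 123 and 566 by limma on TPM.

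In CTD10_TAF15 with galactose the structural GAL genes did not pass against wild type either. GAL1 stood at 18950 ± 3160 CPM with a log2 change of -0.33 ± 0.20 (adjusted p = 0.343), GAL10 at -0.33 ± 0.38, GAL2 at -0.17 ± 0.33 and GAL7 at -0.59 ± 0.22 (adjusted p = 0.0884). Of these GAL7 passed with the replicate number as a block (-0.58, adjusted p = 0.0122). GAL3 was lower at -1.11 ± 0.17, the single call among 11 GAL regulon genes, also when adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.293 with an estimated correlation). Of 25 Gcn4 targets 12 were higher, 17 when adjusted over the list alone, with HIS4 at 2.11 ± 0.34 and CPA1 at 1.31 ± 0.19 (camera adjusted p = 4.03e-12, and adjusted p = 0.293 with an estimated correlation). Of 10 G2/M genes 7 were higher, 8 when adjusted over the list alone, with CDC5 at 0.59 ± 0.11 and HST3 at 0.64 ± 0.13 (camera adjusted p = 4.3e-05, and adjusted p = 0.293 with an estimated correlation). Genes of daughter-cell separation driven by Ace2 were lower, 6 of 9 and 6 when adjusted over the list alone, with EGT2 at -0.66 ± 0.15 (camera adjusted p = 0.00119, and adjusted p = 0.366 with an estimated correlation). RDS1 was at -5.39 ± 0.69, COS10 at -4.67 ± 0.55 and ADH7 at least 66.8-fold lower, and ALD4 and ARO10, of aromatic amino acid breakdown, were higher at 2.94 ± 0.65 and 2.67 ± 0.57. In all, 272 genes were higher and 432 lower, 704 together, of which 683 had no overlap, against 34.3% of all tested genes and 10% by chance. The count ran from 426 (without wild type with galactose replicate 2) to 638 (without CTD10_TAF15 with galactose replicate 1), with 3 of 6 over 1.5 times from the full count, and was 1290 in the blocked fit (585 higher and 705 lower). The balance of directions was 398 higher and 480 lower by DESeq2 and 129 and 493 by limma on TPM.

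The 3 mutants changed many genes in common relative to wild type. Without galactose 112 genes were higher and 312 lower in all 3, and with galactose 170 and 290, while 59 genes were higher and 165 lower in all 6 comparisons. HIS4, CPA1 and DUR12 were among the former and ADH7, COS10, STE3, DMC1, AXL1 and FAR1 among the latter. The CTD10 and CTD10_FUS changes without galactose had a correlation across genes of 0.864. It was 0.5 in simulated data with no strain effect and the same shared wild-type libraries. There were 434 lower genes in common, against 80.2 for independent calls. The simulation gave each gene 1 spread in all groups and drew genes independently of each other. The real wild-type libraries without galactose differed more among themselves than those of CTD10, so 0.5 can be too low a reference. The 80.2 does not allow for the shared wild-type libraries. The other correlations within a medium were 0.791 to 0.878 (simulated 0.49 to 0.51), and pairs of comparisons from different media, which share no library, gave 0.49 to 0.671. Over genes with a mean of at least 10 CPM the latter fell to 0.234 to 0.559. Genes are not independent replicates, so these correlations carry no p. No gene was called in opposite directions by 2 mutants within a medium. The shared wild-type libraries enter every comparison, the wild-type strain alone was labelled as lacking the KAN marker, and each genotype is given as a single strain, so a marker or isolate difference stays within these counts.

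**Figure D3:**
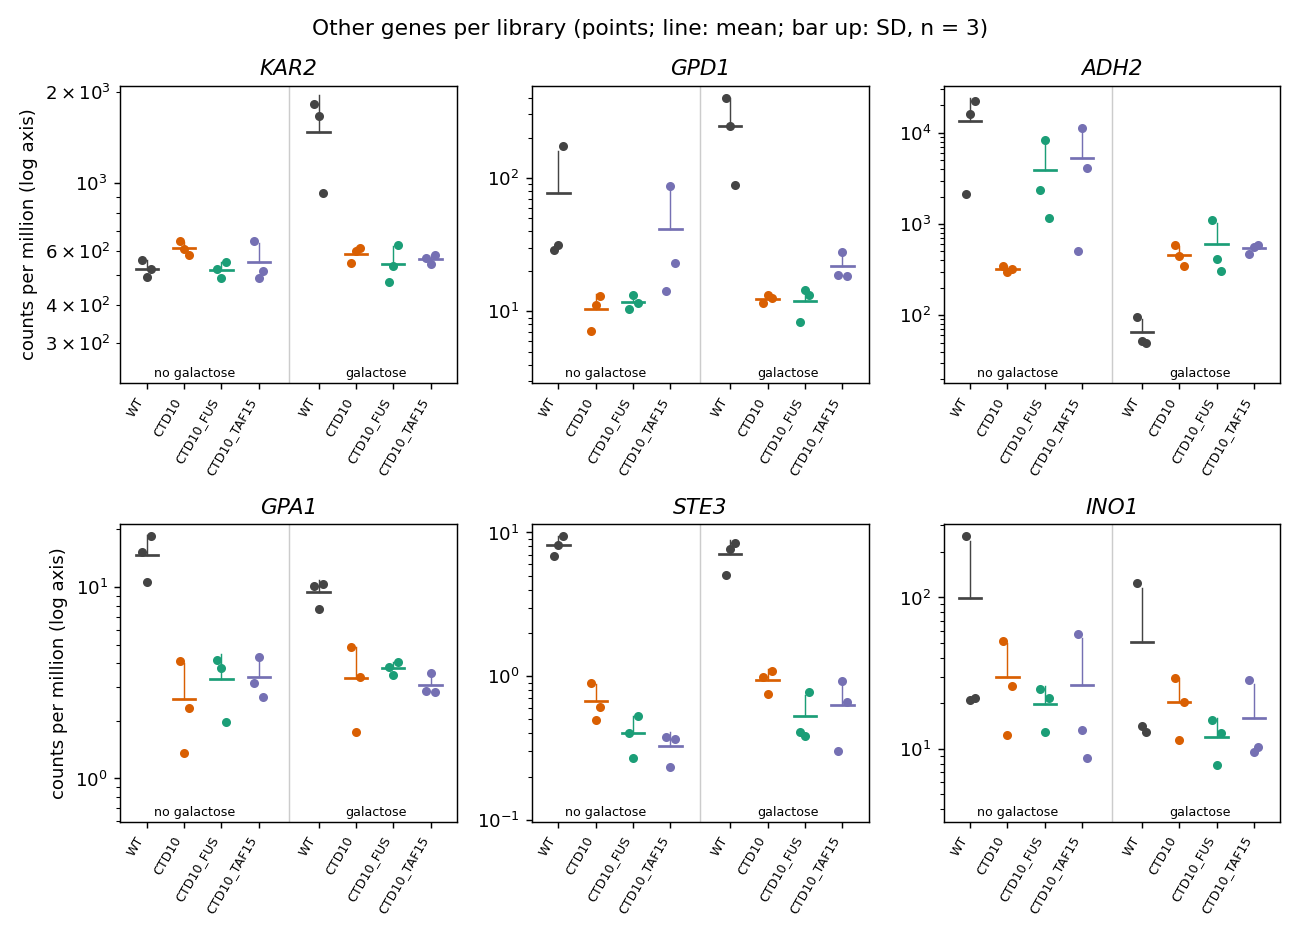
Normalised read counts (CPM) of KAR2, GPD1, ADH2, GPA1, STE3 and INO1 on log axes, by strain and medium, with points for single libraries, horizontal lines for group means and bars of 1 SD upward (n = 3). GPA1 and STE3 lie lower in the mutants in both media, KAR2 is higher in wild type with galactose, and ADH2 and INO1 spread widely between libraries of 1 group.

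CTD10_FUS, with the FUS low complexity domain added, was compared with CTD10 itself. Each is given as a single strain, so an isolate difference and an effect of the domain cannot be told apart. Without galactose YDR042C (YDR042C) fell from 26.8 ± 1.33 in CTD10 to 1.78 ± 0.394 CPM in CTD10_FUS (log2 -3.90 ± 0.41), near the wild-type level of 1.03 ± 0.672. HEM4 (YOR278W), of heme synthesis, was lower at -1.22 ± 0.11, and CTO1 (YCR015C) fell from 63.5 ± 4.19 to 25.8 ± 2.40 CPM (log2 -1.30 ± 0.12). SWI1 (YPL016W), a subunit of the SWI/SNF remodeller, rose from 102 ± 6.20 to 183 ± 7.35 CPM (log2 0.84 ± 0.12; wild type 186 ± 42.8). In all, 10 genes were higher and 24 lower, 34 together, with 643 at an unadjusted p under 0.05. Without 1 library the count was 12 to 26 and over 1.5 times from the full count in 5 of 6 fits, lowest without CTD10_FUS without galactose replicate 3 and highest without CTD10 without galactose replicate 3. DESeq2 called 110 genes (52 higher and 58 lower), the blocked fit 122 (56 and 66) and a fit to these 6 libraries 7.

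With galactose, GAL1 was higher in CTD10_FUS than in CTD10 (log2 1.05 ± 0.20, adjusted p = 0.0132), while GAL10 at 1.21 ± 0.38 (adjusted p = 0.226), GAL2 at 1.08 ± 0.34 and GAL7 at 0.58 ± 0.22 did not pass. With the replicate number as a block GAL10 (1.18, adjusted p = 3.55e-04) and GAL2 (1.05, adjusted p = 0.00152) passed and GAL7 did not. Of the 11 GAL regulon genes 1 was higher, 6 when adjusted over the list alone (camera adjusted p = 2.1e-07, and adjusted p = 0.0276 with an estimated correlation). The GAL1 call ended in 4 of 6 fits without 1 library, with adjusted p = 0.117 without CTD10 with galactose replicate 1 (log2 0.94). CTP1 (YBR291C), the mitochondrial citrate carrier gene, was higher at 127 ± 13.5 against 45.2 ± 7.04 CPM (2.82-fold; adjusted p = 0.0594 without CTD10 with galactose replicate 2). YDR042C was at -3.35 ± 0.39 and UBX6 (YJL048C) at -2.04 ± 0.34 (adjusted p = 0.0629 without CTD10_FUS with galactose replicate 2). Glycolytic genes were higher as a list, 2 of 16 and 4 when adjusted over the list alone (median 0.68, camera adjusted p = 1.06e-11, and adjusted p = 0.215 with an estimated correlation). In all, 11 genes were higher and 23 lower, 34 together, with 545 at an unadjusted p under 0.05. The count was 6 without CTD10 with galactose replicate 2 and 28 without CTD10_FUS with galactose replicate 1, the lowest and highest, and 4 of 6 were over 1.5 times from the full count. The blocked fit, with same-numbered samples resembling each other, called 117 genes (56 higher and 61 lower), DESeq2 81 (36 and 45) and limma on TPM 89 (9 and 80), so the balance of directions depended on the tool and the scaling.

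CTD10_TAF15 gave few calls against CTD10. Without galactose YDR042C, HEM4 and CTO1 were lower, as in CTD10_FUS. Both comparisons share the CTD10 libraries, so a trait of the CTD10 isolate and an effect of the domains cannot be told apart. Without galactose YDR042C was lower at -3.77 ± 0.40, HEM4 at -1.27 ± 0.11, CTO1 at -1.09 ± 0.12 and TRS31 (YDR472W), of a vesicle tethering complex, at -1.03 ± 0.15, from 93.8 ± 14.9 to 45.8 ± 2.79 CPM. In all, 4 genes were higher and 10 lower, 14 together, with 846 at an unadjusted p under 0.05. The count ran from 6 (without CTD10 without galactose replicate 2) to 238 (without CTD10_TAF15 without galactose replicate 1), with 4 of 6 over 1.5 times from the full count. DESeq2 called 106 genes, of which 66 were higher and 40 lower, and the blocked fit 59 (27 and 32). With galactose YDR042C was at -3.64 ± 0.40, HEM4 at -1.11 ± 0.11 and UBX6 at -2.02 ± 0.34, a call that ended in 2 of 6 fits without 1 library (adjusted p = 0.0872, log2 -1.99, without CTD10_TAF15 with galactose replicate 2). GAL1 did not pass at 0.85 ± 0.20 (adjusted p = 0.112), nor did GAL10 at 0.92 ± 0.38, GAL7 at 0.53 ± 0.22 or GAL2 at 0.81 ± 0.33. With the replicate number as a block GAL1 (0.85, adjusted p = 0.0149), GAL10 (0.90, adjusted p = 0.00575) and GAL2 (0.81, adjusted p = 0.0162) passed. The GAL regulon had 0 members called, 6 higher when adjusted over the list alone (camera adjusted p = 3.67e-06, and adjusted p = 0.0593 with an estimated correlation). In all, 5 genes were higher and 14 lower with galactose, 19 together, with 481 at an unadjusted p under 0.05. The count was 5 without replicate 2 and 32 without replicate 1 of CTD10_TAF15 with galactose, and all 6 counts over 1.5 times from the full count. DESeq2 called 43 genes and the blocked fit 46.

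CTD10_FUS and CTD10_TAF15 were compared with each other last. The edgeR test called 0 genes without galactose (167 at an unadjusted p under 0.05, 1 by DESeq2) and 0 with galactose (87 at an unadjusted p under 0.05, 0 by DESeq2). Same-numbered samples resembled each other in each medium, and a fit with the replicate number as a block called 0. With galactose, GAL1 averaged 21800 ± 4390 and 18950 ± 3160 CPM, YDR042C 2.93 ± 0.953 and 2.43 ± 0.479 CPM, and HIS4 523 ± 104 and 468 ± 216 CPM. A count of 0 does not show that the strains were alike. Recovery was not simulated for this comparison. In data simulated for CTD10 against wild type without galactose, the test recovered 37.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 92.3% of those changed 4-fold.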

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

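The tests of the libraries' state and of the library totals in the low genes, the later versions of the genomic DNA test, and all tests on the carbon genes (library state, swap, short CTD) were chosen only after the results were seen. The list of unfolded protein response targets was drawn up after KAR2, JEM1 and MCD4 had been called, but before its own result. Results are listed here because the response to galactose differed between strains by an interaction test in edgeR. It differed between CTD10 and wild type for 88 genes, between CTD10_FUS and wild type for 3 and between CTD10_TAF15 and wild type for 2. In CTD10 the interactions with the largest sizes among named genes were ACS1 at 9.27, ADH2 at 8.21, FDH1 at 7.84, RGI2 at 7.63 and FOX2 at 7.39, of which ADH2 and FDH1 share reads with other targets and are uncertain. On the negative side were CMK2 at -2.18, FUR4 at -2.14, DIA1 at -2.001, YLR257W at -1.72, IME1 at -1.72 and GAL80 at -0.93. In CTD10_FUS they were KAR2 at -1.42, MCD4 at -1.41 and JEM1 at -0.93, and in CTD10_TAF15 KAR2 at -1.45 and JEM1 at -0.90.

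Genes of low expression were lower in the mutants than in wild type: without galactose 145 genes with a mean under 10 CPM were lowered by all 3 mutants, and 31.2, 19.5 and 12.7% of genes at 1 to 3 CPM were lower in CTD10, CTD10_FUS and CTD10_TAF15, against 4.77, 1.77 and 2.32% of genes above 300 CPM. The pattern was not as clear in genes under 1 CPM, of which 17.1, 6.1 and 7.32% were lower without galactose (medians -0.17, -0.019 and -0.041), and with galactose the medians of another set, 50 genes under 1 CPM in wild type without galactose, were 0.76, 0.38 and 0.66. The tables argue against more reads in wild type, since its highest total without galactose was 1.14 times the lowest of the mutants. The smallest of the medians at 1 to 3 CPM is a 1.37-fold fall, more than that ratio would give even with no scaling. Fold changes are scaled to the library totals, so a ratio of totals does not enter them directly. Thinning to 1 total moved the CTD10 median only from -0.582 to -0.60, which tests nothing. For the 145 genes the tables also argue against the state of the wild-type libraries without galactose. With galactose the highest of the 3 medians over these genes was still -1.74. Among genes at 1 to 3 CPM in wild type without galactose, 12.3, 14.3 and 12.8% were lower with galactose. Their medians were -0.28, -0.25 and -0.32, against -0.59, -0.58 and -0.45 for the 1 to 3 CPM set used without galactose. The 2 sets differ, so a part of library state in the wider pattern stays open. Genomic DNA in the wild-type libraries was tested in 3 versions, the later ones after the earlier results and the counts used had been seen: the first, 29 targets over 1 kb at 0 counts, met its bound, but 21 of them share reads and 16 have no count in any library, so 0 of 29 are informative and the bound was wrong. The next found 4 targets against 3.07 and the last 40 against 4.84e-10, but the last took its excess from the 145 genes picked as lowered. The median excess in wild type was 6.52 CPM per kb over those genes and 0.956 over all 303 low genes. Of the 145 genes 137 had over 2 times the excess of the low genes. They were picked as lowered in these same libraries, which favours a large excess, so that count decides nothing. For the 145 genes and for genes of low expression at large, genomic DNA and a change of expression cannot be told apart. The KAN marker, the single isolates and the short CTD stay open as untested.

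Genes of carbon source use were lower with galactose in wild type, with ADH2 from 2140, 16300 and 22500 CPM in the 3 libraries without galactose. A swap of libraries between the media is argued against by the lowest GAL share with galactose, 1.87%. The state of single libraries and galactose cannot be told apart, since the spread within groups without galactose was 1.08 times that with galactose, with a 95% interval of 0.512 to 2.27. The interval was added after the result was seen and includes the ratio of 2 predicted for a library state. A comparison of CTD10 with wild type without galactose gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow, and it has no bearing on a fall within wild type.

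KAR2, JEM1 and MCD4 were higher with galactose in wild type, and the rise was smaller in the mutants except that the MCD4 interaction did not pass in CTD10_TAF15. For CTD10_FUS a single wild-type library is argued against, since the smallest interaction without 1 library kept 0.872 of its size. The KAR2 call nevertheless ended in 9 of 12 fits without 1 library. CTD10 and CTD10_TAF15 were not tested in this way. The data are consistent with a rise of targets of the unfolded protein response as a group in wild type: over 12 other listed targets the highest of the 3 interaction medians was -0.67, and all 12 were negative in each mutant. The 3 interactions subtract the same wild-type response, in which all 12 targets rose. Their shared sign in the 3 mutants thus repeats 1 wild-type change and is not independent evidence. Of single targets 9 of the 12 passed as higher in wild type, while EUG1, FPR2 and HRD3 did not. Of 36 interactions 2 passed, LHS1 and MPD1 in CTD10. A biological reading stays a hypothesis, since the wild-type strain also differs in its marker label.

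Other splits of the libraries test whether an arbitrary grouping gives as many genes. For each comparison of 3 against 3 libraries, fitted to those 6 libraries alone, the 10 splits are too few for a share under 0.05. The real count was as large as any in 1 of 10 splits for these: galactose in wild type (27 genes, highest other 0), in CTD10 (17 and 12), CTD10_FUS (24 and 0) and CTD10_TAF15 (11 and 0). The same held without galactose for CTD10 (354 and 0), CTD10_FUS (106 and 40) and CTD10_TAF15 (46 and 0) against wild type, and with galactose (1197 and 0, 775 and 0, 607 and 0). Against CTD10 the values were 7 and 0 without and 57 and 1 with galactose for CTD10_FUS, and 2 and 0, and 7 and 1, for CTD10_TAF15. CTD10_FUS against CTD10_TAF15 gave 0 genes (edgeR, all libraries: 167 and 87 at an unadjusted p under 0.05, DESeq2 1 and 0), all 10 splits were as large in each medium by definition, and the highest others were 16 and 1. Where same-numbered samples resembled each other, splits that parted all pairs gave at most 0. Of 100 interaction splits, 3 were as large as the real 31 for CTD10 against wild type, the real one included. That share is under 0.05 for this fit, but it does not exclude chance. The highest other split called 1512, and the reason was not examined. Splits can swap strains within 1 medium, so they are no reference free of strain effects. For the other interactions the real count was 0, so 100 of 100 were as large by definition and the splits say nothing about chance, with highest others of 893, 275, 317 and 883.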

How the results depend on the processing

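Alternatives were planned, except the fit without the high-ADH2 libraries, which was chosen after seeing the data. Named genes were refitted under 8 settings, not under the fold minimum. Over these 6592 of 8369 values of called genes kept their call, 1777 fell short of the threshold and 0 reversed, and of 403 values of uncalled genes 28 passed and 16 changed sign. DESeq2 kept 654 of 655 called values, RLE factors 650, no low-count filter 640, TPM 546, the compared libraries alone 322 of 648, leave-one-out fits 2920 of 4026 and the fit without high-ADH2 libraries 205 of 420. TPM moved the median of all genes by more than 0.1 in 10 comparisons, at most by -0.23, and other scalings by at most 0.02. The cause was not tested for any change below, except that a fold minimum calls fewer genes by construction.

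DESeq2 called 232 and 892 genes for galactose in CTD10_FUS and CTD10_TAF15, 110 and 106 for CTD10_FUS and CTD10_TAF15 against CTD10 without galactose, 81 and 43 with galactose, 1 for CTD10_FUS against CTD10_TAF15 without galactose, and 320, 28 and 36 for the interactions of CTD10, CTD10_FUS and CTD10_TAF15 with wild type. TPM with limma gave 277 and 960 for galactose in CTD10_FUS and CTD10_TAF15, 89 for CTD10_FUS against CTD10 with galactose, and 15 and 1 for the interactions of CTD10 and CTD10_TAF15. In it GAL2 in CTD10_FUS against wild type with galactose reversed to -0.025. With a fold minimum of log2 1 the counts were 350, 30 and 130 for galactose in wild type, CTD10_FUS and CTD10_TAF15, 546, 326 and 246 for CTD10, CTD10_FUS and CTD10_TAF15 against wild type without galactose and 285, 263 and 230 with galactose, 14 and 9 without and 11 and 9 with galactose against CTD10, and 55 and 1 for the interactions of CTD10 and CTD10_TAF15.

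With the replicate number as a block, which allows for the pairing, the counts were 2086, 23, 239 and 1397 for galactose in wild type, CTD10, CTD10_FUS and CTD10_TAF15, 2369, 1204 and 1050 against wild type without galactose and 1539, 1299 and 1290 with galactose, 122, 59, 117 and 46 for the comparisons with CTD10, and 373, 12 and 19 for the interactions with wild type. The blocked fit ended 0 of 655 calls of named genes, and 11 of 33 uncalled values passed under it, all of them of RPO21 or GAL genes and each given beside its comparison. The compared libraries alone gave 27, 24 and 11 for galactose in wild type, CTD10_FUS and CTD10_TAF15, 354, 106 and 46 against wild type without galactose, 7 and 2 without and 57 and 7 with galactose against CTD10, and 31, 0 and 0 for the interactions. Without high-ADH2 libraries the counts were 84 and 154 for galactose in wild type and CTD10_FUS, 549, 205 and 248 against wild type without galactose, and 0, 0 and 0 for the interactions, and PGM2 in wild type with galactose reversed to 0.26. That fit leaves 1 wild-type library without galactose, assumed to vary like the other groups. List tests passed in 11 cases with an estimated correlation and 243 with the block. Strain effects compared across media gave correlations of 0.52, 0.49, 0.612, 0.593, 0.639 and 0.65, and of 0.251, 0.234, 0.451, 0.373, 0.505 and 0.516 over genes with a mean of at least 10 CPM.

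Leaving out 1 library gave these lowest and highest counts: 379 and 2388 for galactose in wild type, 13 and 14 in CTD10, 15 and 40 in CTD10_FUS, 19 and 1192 in CTD10_TAF15. Against wild type they were 858 and 2526, 406 and 1474, 370 and 926 without galactose and 578 and 785, 479 and 611, 426 and 638 with galactose for CTD10, CTD10_FUS and CTD10_TAF15. Against CTD10 they were 12 and 26, and 6 and 238, without galactose and 6 and 28, and 5 and 32, with it, for CTD10_FUS and CTD10_TAF15. CTD10_FUS against CTD10_TAF15 gave 0 and 1 without galactose. Interactions with wild type gave 4 and 1037, 1 and 22, and 0 and 15. The count of 1 came without CTD10_FUS without galactose replicate 1. Except for this comparison and for galactose in CTD10, the libraries are named with each count beside the comparisons. Reversed values were those of genes not called: PCL10 -0.18 and INO1 1.25 for galactose in wild type, and INO1 0.50 and 0.32 in CTD10 and CTD10_TAF15 without galactose, all without wild type without galactose replicate 1. INO1 was 0.58 and 0.23 in CTD10 and CTD10_TAF15 with galactose without wild type with galactose replicate 1. In CTD10_FUS with galactose GAL2 was -0.13, -0.06 and -0.05 (without wild type replicate 1, CTD10_FUS replicate 2 and CTD10_FUS replicate 3), GAL10 was 0.08, 0.08 and 0.21 (without wild type replicates 2 and 3, and CTD10_FUS replicate 1) and GAL1 was 0.030 (without CTD10_FUS replicate 1). GAL2 in CTD10_TAF15 was 0.044 without CTD10_TAF15 with galactose replicate 1. The other ends of these ranges were 0.44 for PCL10 and -2.87 for INO1 with galactose in wild type, and -2.38 and -3.17 for INO1 without and -1.77 and -2.36 with galactose in CTD10 and CTD10_TAF15. They were -0.26 for GAL1, -0.24 for GAL10 and 0.38 for GAL2 in CTD10_FUS and -0.40 for GAL2 in CTD10_TAF15. Depth limits genes with few counts.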

Other observations

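No test in this part was chosen after its result was seen. Phosphate genes stood higher in CTD10_FUS than in CTD10_TAF15 with galactose as a list. Of 13 tested 0 were called and 6 were higher when adjusted over the list alone (median 0.85, camera adjusted p = 7.6e-19, and adjusted p = 0.0204 with an estimated correlation). PHO84, the phosphate transporter gene, was at 2.56 ± 0.69 and did not pass. It stood at 835, 217 and 122 CPM in the 3 CTD10_FUS libraries with galactose and at 66.5 ± 8.18 CPM in CTD10_TAF15, and its log2 change was 1.35 without CTD10_FUS with galactose replicate 1. Ace2 targets of daughter-cell separation were higher in CTD10_FUS in the same comparison, with 0 of 9 called and 6 when adjusted over the list alone (median 0.42, camera adjusted p = 1.15e-19, and adjusted p = 0.0127 with an estimated correlation), SCW11 at 0.42 ± 0.16 and BUD9 at 0.39 ± 0.14. The edgeR test called 0 genes there, with 87 at an unadjusted p under 0.05 and 0 by DESeq2.

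The 3 strains with a shortened CTD differed from wild type in opposite directions in 0 genes within a medium and in 1 to 21 genes across media. Principal components of all libraries took 35.8, 21.1 and 11.2% of the variance, and the first component within groups took 40.3%. Replicate 1 libraries resembled each other more than the others, with a mean residual correlation of 0.44 over 28 pairs against 0.18 for same-numbered pairs of replicates 2 and 3.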
